A study of Mus musculus with 4 samples.

How the data were processed

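Crosslinking immunoprecipitation with sequencing (HITS-CLIP) joins proteins to the RNA they touch with ultraviolet light, pulls down the protein with an antibody and sequences the RNA fragments left on it. Per the labels, it was applied to IMP2 (gene Igf2bp2, an RNA-binding protein of the IGF2BP family) in brains of Swiss Webster mouse embryos at E14, with benzonase as the nuclease, and the bands of the protein-RNA complexes were cut from a membrane before sequencing. There were 4 libraries, 2 with R and 2 with M in their titles. Each R library shares a further title code with an M library, and the labels do not explain that code. The protocol names a mouse and a rabbit antibody to IMP2, but the labels do not say what R and M stand for, so the letters were kept as names only.

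The values analysed came from a single list of clusters (peaks of overlapping CLIP tags) for the whole series, annotated by the authors to RefSeq transcripts. Bowtie, FastQC and the genome build mm9 are named, without versions, in the submitters' processing notes. The peak caller, its thresholds, the RefSeq release and whether the 4 libraries were pooled are not given in the sources used here. The deposited cluster height is a signal (pileup) value, read here as the largest number of overlapping tags, and holds whole numbers. Per the file headers, the second score is a fold of the height, a ratio whose reference level the header does not define; dividing height by fold gives an implied denominator between 1 and 12.9. The lowest deposited fold was 2 and the lowest height 18, so clusters under these values do not appear. Both scores are the authors' values for a cluster and were used only to describe, rank and filter clusters. The number of tags in each library is not given in the sources used here, so the depth behind each height is unknown. PCR duplicates affect heights in a way that could not be checked. No column held values of a single library, so R and M libraries were not compared, no replicate error was computed, and no control immunoprecipitation or input library was analysed here. All p-values below compare genes or clusters within the list, and genes are not independent replicates.

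The list held 2865 lines, 1 for each cluster and transcript, which were reduced to 1828 distinct clusters in 1099 transcripts. Starts were converted from 0-based to 1-based, and all coordinates are on mm9. Transcripts were matched by accession (1088) or by gene name (11) to a RefSeq table of GRCm38, used for gene names and for the set of 21900 protein-coding genes, and no coordinate was taken from it; 55 genes took the current symbol. A cluster was assigned to 3' UTR, coding sequence (CDS) or 5' UTR by its midpoint within the deposited region intervals. A gene counted as listed when it had at least 1 cluster, and the level of a gene was its highest cluster. The length of a 3' UTR is that of the longest deposited interval of the gene. Intervals for shares are exact Clopper-Pearson 95% intervals and cover counting error only.

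For 32 gene lists (1124 genes in all, some in more than 1 list), written before the data were examined from general knowledge of the brain and of basic cell functions, listed against unlisted genes were compared with a 2-sided Fisher's exact test against all protein-coding genes. The p-values were adjusted by Benjamini-Hochberg over the 32 lists and called below 0.05. The lists covered axon guidance, adhesion, the cytoskeleton, transport, synapses, channels, progenitors, transcription factors, RNA-binding and ribosomal proteins, translation, energy metabolism, the proteasome, chaperones, the cell cycle, chromatin, signalling, IGF2BP proteins and their reported targets, matrix, and markers of non-neural and glial cells. For the 16 lists with at least 5 listed members, the median height was compared with random sets of listed genes of the same size in a 2-sided permutation test (100000 draws), adjusted over these lists. The position of clusters within 3' UTRs was compared with 10000 random re-placements of each cluster in its own interval, a 2-sided permutation test chosen after the data were examined, and the share in the first and last of 10 equal parts was tested in the same way once the counts of these parts had been seen. The alternatives were clusters taller than the median height, genes with at least 2 clusters, the union of the fixed lists as background, joined clusters, other rules for the region, and other gene levels. Backgrounds of genes with an NM accession, genes with a 3' UTR cluster, genes that share a cluster counted once, fold in place of height, joining at up to 50 bases and other settings of the position test were added after the data were examined.

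Genes were named by a rule set before the data were examined. It took the 12 genes with the highest cluster, the 8 with the most clusters, 2 to 4 listed members with the highest clusters of each list that passed or held cell markers, and the IGF2BP family, Actb, Igf2 and Robo1. Some genes that the rule takes are not reported here. Genes named outside it were chosen after their values were seen.

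Several planned parts were left out. The chance share of each transcript region and a background matched on transcript length need boundaries of whole transcripts on mm9, motif tests need the mm9 sequence, and agreement of libraries needs values for each library; none of these was used here. The list test was tested on 40 simulated gene sets: it called 96.5% of lists whose genes were listed 8 times as readily as others, 29% at 3 times, none at 0.2 times and 1.11% of lists with no difference. A list that is depleted against all genes would thus be missed. The position test, for the mean position only, called 20 of 20 simulated shifts towards each end and 0 of 20 uniform sets. Those shifts were strong. Weaker shifts and the shares near the ends were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.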

Results

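The RNA bound by IMP2, an RNA-binding protein of the IGF2BP family, was mapped by HITS-CLIP in E14 mouse brain to find the transcripts it contacts while axon tracts form. A single list of clusters stood for the 4 libraries (2 with R and 2 with M in their titles), so values carry no replicate error and the 2 kinds of library were not compared. It held 1828 clusters in 761 genes, which is 3.47% of the protein-coding genes. The median cluster height was 30 (interquartile range 24 to 39, full range 18 to 107). The authors' fold of the height had a median of 5.4 and a maximum of 25.5, and the median cluster width was 53 bases.

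The highest cluster of the list lay in the 3' UTR of Nnat, which encodes the small membrane protein neuronatin, on chromosome 2 at positions 157387626 to 157387779 (mm9, plus strand). It had a height of 107. Nrep (D0H4S114 in the list), a neuronal protein linked to regeneration, followed with a height of 106 on chromosome 18 at 33597983 to 33598291. Dpysl2, encoding the tubulin-binding collapsin response mediator CRMP2, reached 96 on chromosome 14 at 67421866 to 67422256. A height of 94 was shared by the translation initiation factor gene Eif4g2 (chromosome 7, 118215679 to 118215933), the haem-binding membrane protein gene Pgrmc1 (chromosome X, 34145274 to 34145576) and the reticulon gene Rtn1 (chromosome 12, 73312745 to 73313033). Cd24a, a surface glycoprotein of immature neurons, reached 92 on chromosome 10 at 43303183 to 43303246. Lars2, the mitochondrial leucyl-tRNA synthetase, reached 91 on chromosome 9 at 123371081 to 123371130, and its fold of 17.7 was the highest among these 12 genes; whether repeated or rRNA-like sequence adds tags to this cluster, only 50 bases wide, was not tested. Map1b (microtubule-associated protein 1B, listed as Mtap1b; chromosome 13, 100195443 to 100195709), the fatty acid desaturase gene Scd2 (chromosome 19, 44380719 to 44380990) and the transcription factor gene Sox11 (chromosome 12, 28022301 to 28022676) each had a height of 90. Ttr, which encodes the thyroid hormone carrier transthyretin of the choroid plexus, closed the group with 88 on chromosome 18 at 20832144 to 20832385. All 12 of these clusters lay in 3' UTRs by their midpoint, and that of Ttr began upstream of its 3' UTR interval, which starts at 20832240. The genes with the highest folds were others: the tetraspanin gene Tspan18 (25.5), the pericyte gene Rgs5 (23.1) and Usf3 (22.0, listed as Gm608), named after their values were seen.

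**Figure D1:**
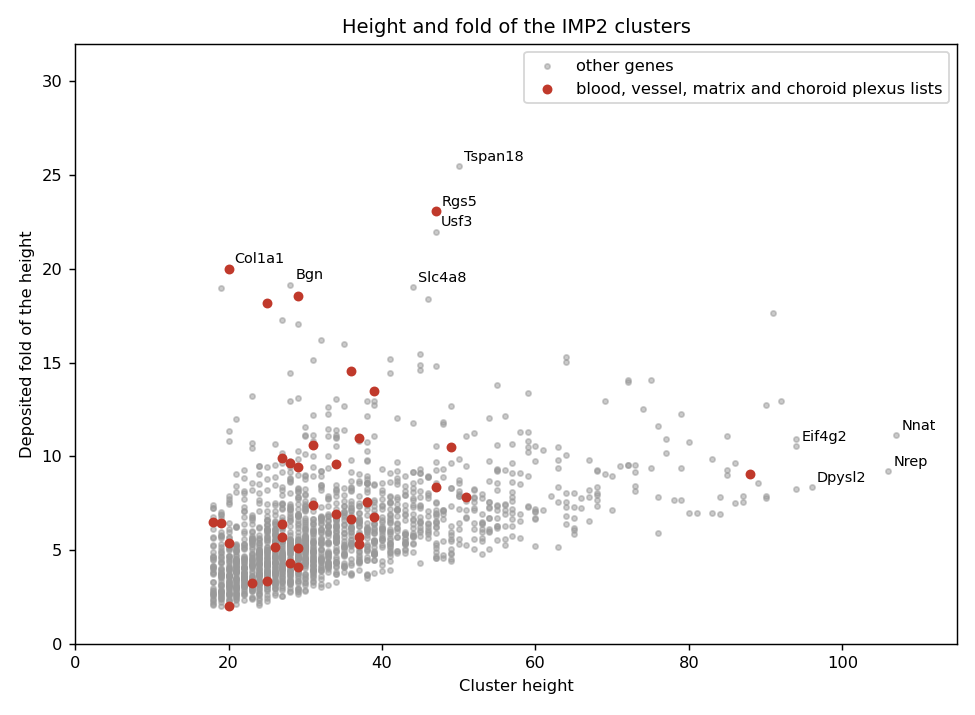
Each point is 1 of the 1828 clusters, with its height on the x axis and the deposited fold of the height on the y axis; red points are clusters in genes of the erythroid, endothelial, meningeal, matrix and choroid plexus lists. Nnat (height 107) is at the far right, and the highest fold, at Tspan18 (25.5), belongs to a cluster of height 50.

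IMP2 clusters lay almost entirely in 3' UTRs. Of the 1828 clusters, 1721 (94.1%, 95% interval 93.0 to 95.2) were in a 3' UTR, 99 (5.42%, 4.42 to 6.55) in the CDS and 8 (0.438%, 0.189 to 0.860) in a 5' UTR. Among the 857 clusters taller than the median height, the CDS held 3.38% and 5' UTRs 0.233%. Eif4g2 and Map1b were exceptions in part, each with 7 clusters in the CDS beside 4 and 18 in the 3' UTR. Kmt2e (Mll5 in the list), the tubulin gene Tubb5 and the ubiquitin ligase gene Huwe1 had 4 CDS clusters each, and Huwe1 had no other cluster. The clusters in 5' UTRs belonged to Tuba1a, Tubb5, Nnat, the ferritin gene Ftl1, the transcript-export factor gene Chtop, Tulp4 and, with a pair, BC005537. All genes of the last 3 sentences except those of the naming rule were chosen after their values were seen. These shares were counted without a test, since the expected share of each region from its length was not computed, and only clusters within annotated mRNA were listed.

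Clusters lay along the whole 3' UTR, with no preference for either end that the tests could detect. The mean position of the 1721 clusters was 49.2% of the way from the stop codon to the 3' end, against 50% ± 0.669 (SD over 10000 re-placements) for random placement within the same 3' UTRs (2-sided permutation test, p = 0.21, adjusted p = 0.433 over 3 measures). The first 200 bases held 9.41% of clusters against 9.96% (permutation adjusted p = 0.433) and the last 200 bases 10.6% against 9.98% (permutation adjusted p = 0.433). With the 3' UTR cut into 10 equal parts, each part held between 133 and 201 clusters, and the lowest counts were those of the first (140) and last (133) parts. Together these outer parts held 15.9% of clusters against 16.8% ± 0.889 (SD) on random placement, where the width of a cluster keeps its midpoint off the ends (2-sided permutation test, p = 0.317, chosen after the counts were seen).

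**Figure D2:**
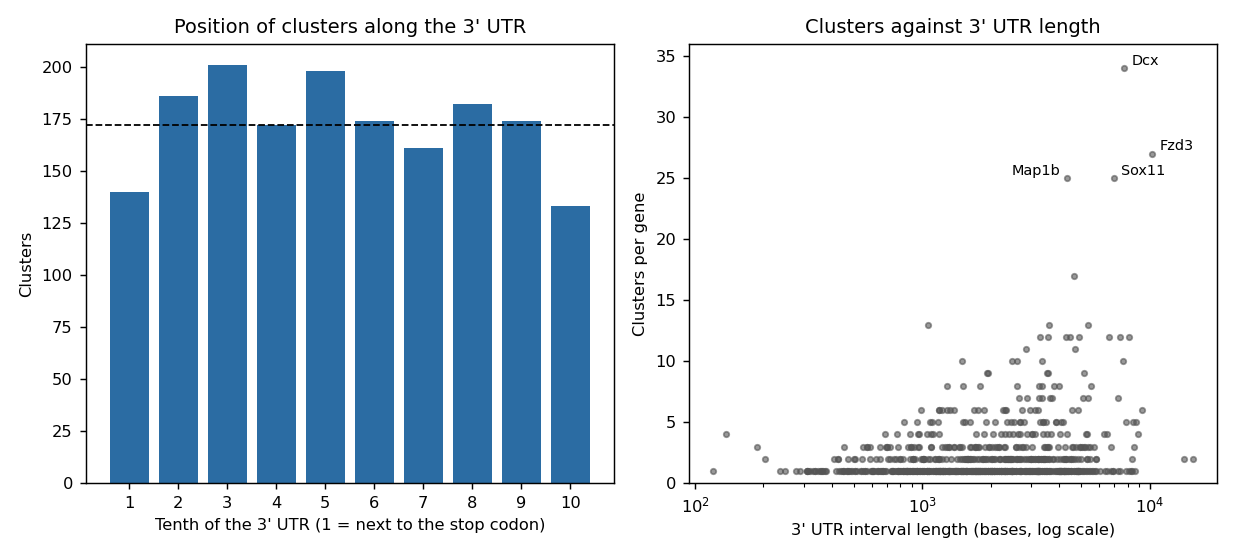
Left, the number of clusters (y axis) in each of 10 equal parts of the 3' UTR from the stop codon to the 3' end (x axis), with the mean as a dashed line; right, the clusters of each of 729 genes (y axis) against the length of its 3' UTR in bases on a log scale (x axis). The first (140) and last (133) parts are the lowest, and Dcx, with 34 clusters, is the highest point on the right.

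A few transcripts of developing neurons carried many separate clusters. Dcx, which encodes the microtubule-associated protein doublecortin of migrating neurons, had 34, all in its 3' UTR, and they covered 41.6% of it. Its highest cluster (height 85) lay on chromosome X at 140294923 to 140295001. Fzd3, a Frizzled receptor gene needed for axon tract formation, had 27 clusters with a maximum height of 55 at 65814666 to 65814736 on chromosome 14. Sox11 and Map1b had 25 each, and the clusters of Map1b covered 74.1% of its 3' UTR. The cyclin gene Ccnd2 of neural progenitors had 17, while Tubb5, the kinesin gene Kif5c and the phosphate exporter gene Xpr1 had 13 each. By contrast, 419 genes (55.1%) had a single cluster, and the 37 genes with at least 8 clusters held 452 of them (24.7% of all). Joining clusters of a gene that lay at most 50 bases apart moved several of these counts by over 1.5 times: Dcx fell to 18 clusters, Sox11 and Map1b to 15 and Tubb5 to 6, while Fzd3 kept 25.

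**Figure D3:**
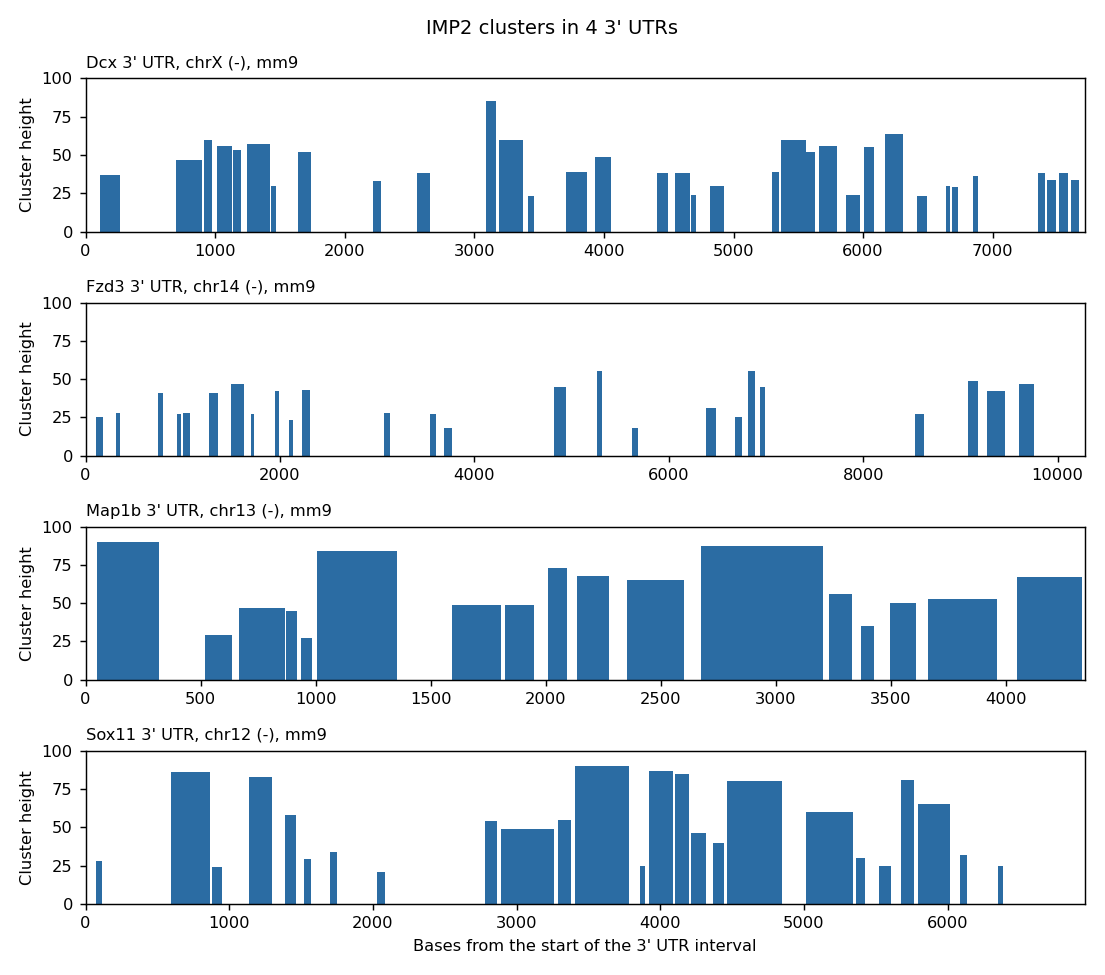
Clusters in the 3' UTRs of Dcx, Fzd3, Map1b and Sox11; the x axis gives bases from the start of the 3' UTR in the direction of transcription, and each bar has the width and height of a cluster. In Dcx and Fzd3 the clusters are scattered over the whole 3' UTR, and in Map1b they cover 74.1% of it.

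Genes of the cytoskeleton and of guidance signalling inside the growth cone were often listed. Among tubulins and microtubule proteins, 18 of 46 carried a cluster (39.1%, 95% interval 25.1 to 54.6, against 3.47% of all protein-coding genes), with an odds ratio of 18.3 (Fisher's exact test, adjusted p = 1.27e-13). The tallest clusters of this group were at Map1b (90), Dcx (85), the microtubule-destabilising stathmin gene Stmn2 (85) and the dendritic microtubule protein gene Map2 (64). The actin list had 14 of 44 (31.8%, odds ratio 13.2, Fisher's exact adjusted p = 9.30e-10), led by Marcks (79), which links membranes to actin, the actin-sequestering thymosin gene Tmsb4x (76), the profilin gene Pfn2 (63) and Marcksl1 (60). Guidance effectors, the proteins that carry guidance signals to the growth cone, had 15 of 47 (31.9%, odds ratio 13.3, Fisher's exact adjusted p = 2.42e-10), among them Dpysl2 (96), Dpysl5 (41), the kinase gene Gsk3b (39) and the actin polymerase gene Enah (38). These 3 groups also passed against the other fixed-list genes, of which 14.9%, 15.3% and 15.2% were listed beside the microtubule, actin and effector lists. Their odds ratios fell to 3.66, 2.59 and 2.61 in that comparison, and the adjusted p-values of Fisher's exact test, the highest of any alternative, were 0.000995, 0.0395 and 0.0349. The other fixed-list genes include 197 ribosomal, oxidative phosphorylation, glycolysis and proteasome genes, of which 1.52% were listed. This lowers the share that the groups were compared with.

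Receptors and ligands of axon guidance were listed less densely than those effectors, a difference that was not itself tested. Of 51 guidance receptor genes, 9 carried clusters (17.6%, odds ratio 6.01, Fisher's exact adjusted p = 0.000185). They included the netrin receptor gene Dcc (height 67, 7 clusters), Fzd3 (55), the plexin gene Plxna2 (44) and the receptor phosphatase gene Ptprs (44). Robo1, a receptor for the midline repellent Slit, had 2 clusters in its 3' UTR, the higher one of height 31 and fold 4.98 on chromosome 16 at 73045047 to 73045209. Of 47 guidance ligand genes, 7 did (14.9%, odds ratio 4.90, Fisher's exact adjusted p = 0.00238), with Reln (46), which encodes reelin, at the top, followed by Rgma (33), Sema6a (31) and Sema6d (23). Neural adhesion molecules had 7 of 43 (16.3%, odds ratio 5.44, Fisher's exact adjusted p = 0.00147), among them Ncam1 (73, 12 clusters), Itgb1 (41) and Nlgn3 (36). None of these 3 lists passed against the other fixed-list genes, where their odds ratios were 1.14, 0.921 and 1.03, and the ligands also lost the call with taller clusters and with genes of at least 2 clusters. Genes of axonal motors (4 of 36), presynaptic proteins (4 of 39), postsynaptic proteins (2 of 41) and voltage-gated channels (2 of 37) did not pass (Fisher's exact adjusted p = 0.0595, 0.0728, 0.721 and 0.493). The motors passed when only clusters taller than the median height, or only genes with at least 2 clusters, were counted.

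Regulators of neuronal identity and of RNA were also often listed. Neurogenic and neuronal transcription factors had 18 of 47 (38.3%, odds ratio 17.6, Fisher's exact adjusted p = 1.27e-13), among them Sox11 (90), Tcf4 (64) and Nfib (54). RNA-binding proteins of RNP granules had 19 of 60 (31.7%, odds ratio 13.2, Fisher's exact adjusted p = 8.69e-13), among them the splicing and decay regulator gene Celf2 (57, 12 clusters), the granule protein gene Caprin1 (54) and Pcbp1 (46). Both lists passed against the other fixed-list genes, with odds ratios of 3.53 and 2.62 (Fisher's exact adjusted p = 0.000995 and 0.0105, each the highest of any alternative). Those other genes include the 197 ribosomal, oxidative phosphorylation, glycolysis and proteasome genes, of which 1.52% were listed. Their inclusion lowers the share that both lists were compared with. Whether either call holds without these 197 genes was not tested.

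Further groups passed against all protein-coding genes but not against the other fixed-list genes. Neural progenitor markers had 9 of 37 (odds ratio 9.02, Fisher's exact adjusted p = 1.95e-05), with Ccnd2 (77), the endothelin receptor gene Ednrb (40), Ptprz1 (34) and Pea15a (31). The call was lost when only genes with at least 2 clusters were counted. Wnt signalling had 8 of 39 (odds ratio 7.23, Fisher's exact adjusted p = 0.000172), led by the beta-catenin gene Ctnnb1 (86), Fzd3 (55) and Tcf7l2 (50). Insulin, IGF and mTOR signalling had 8 of 37 (odds ratio 7.73, Fisher's exact adjusted p = 0.000129), with the growth-factor adaptor gene Grb10 (63), Igfbpl1 (63), Igfbp5 (59) and the IGF1 receptor gene Igf1r (47). Chaperones had 6 of 28 (Hsp90aa1 76, Canx 47), translation factors 6 of 39 (Eif4g2 94, Eef2 41) and chromatin regulators 7 of 41 (Smarce1 38, Chd6 33), with odds ratios of 7.63, 5.08 and 5.76 (Fisher's exact adjusted p = 0.000983, 0.00423 and 0.00124). Translation factors and chromatin regulators lost the call with taller clusters alone, and these 3 lists lost it with genes of at least 2 clusters.

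Matrix genes and a few markers of blood and meninges were listed too. Extracellular matrix had 9 of 38 (odds ratio 8.71, Fisher's exact adjusted p = 2.12e-05), including the brain proteoglycan gene Ncan (51), Sparc (49), the basement-membrane collagen gene Col4a2 (39) and Nid1 (37). Erythroid markers had 3 of 17 (odds ratio 5.97, Fisher's exact adjusted p = 0.0372): the globin genes Hba-a1 and Hba-a2, which share a single CDS cluster of height 27, and Hbb-y (23). Meningeal and mesenchymal markers had 3 of 18 (odds ratio 5.57, Fisher's exact adjusted p = 0.0411), namely Zic1 (37), Col3a1 (29) and Col1a1 (20). Against the other fixed-list genes none of these 3 lists passed. The meningeal odds ratio was 7.92 with genes of at least 2 clusters (2 of 18) and 3.10 with taller clusters (Fisher's exact adjusted p = 0.0721 and 0.4). Both marker lists thus lost the call with taller clusters or with genes of at least 2 clusters. The erythroid list also lost it with genes that have a 3' UTR cluster, and its call rested on the shared globin cluster: with that pair counted once, 2 of 16 were listed (Fisher's exact adjusted p = 0.168, range 0.0414 to 1 over the alternatives). Markers of oligodendrocytes and astrocytes (2 of 18, Gja1 at 38 and Slc1a2 at 27), endothelium and pericytes (1 of 20, Rgs5 at 47) and choroid plexus (1 of 12, Ttr at 88) did not pass, and 0 of 18 microglia and macrophage markers were listed (upper 95% limit 18.5%).

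Housekeeping and cell cycle lists had shares on either side of the 3.47% of all protein-coding genes. Ribosomal proteins (1.30%), oxidative phosphorylation (1.45%) and the proteasome (0%) lay below it, and glycolysis (5%) and the cell cycle (7.89%) above it. Of 77 cytosolic ribosomal protein genes, only Rpl7 (27) was listed, of 69 oxidative phosphorylation genes only Atp5a1 (35), of 20 glycolysis genes only Slc2a1 (50) and of 31 proteasome genes none; these single members were named after their values were seen. Cell cycle genes had 3 of 38 (Ccnd2, Rb1 and Top2a). None of these lists was called as different from all protein-coding genes (Fisher's exact adjusted p = 0.624, 0.784, 0.624, 0.716 and 0.21 in that order). In simulations this test called no list whose genes were listed 0.2 times as readily, so it could not show a depletion. Against the other fixed-list genes, ribosomal proteins (odds ratio 0.0642), oxidative phosphorylation (0.0725) and the proteasome (0) were listed less often (Fisher's exact adjusted p = 0.000982, 0.000995 and 0.0395).

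**Figure D4:**
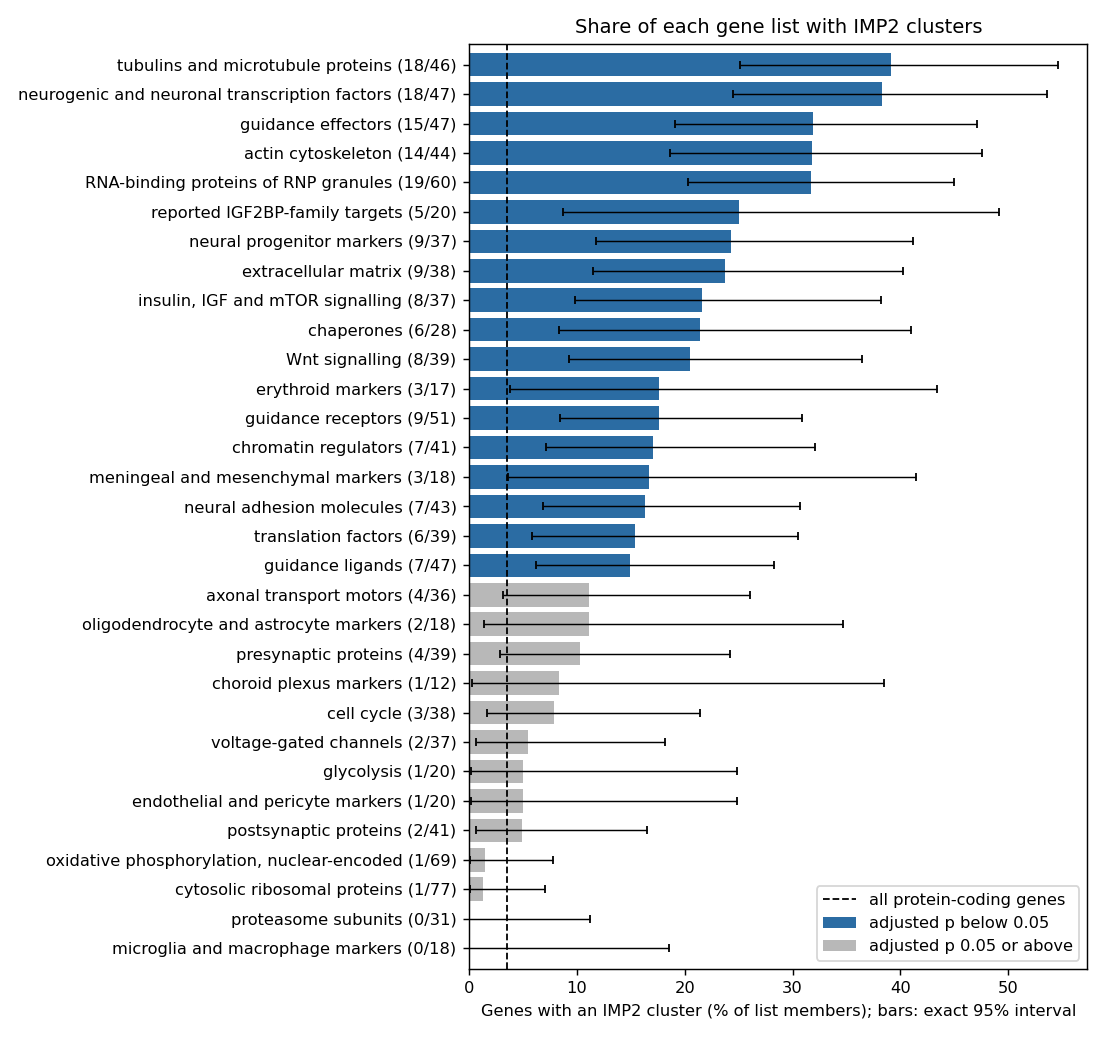
Share of genes with at least 1 IMP2 cluster in each fixed list (x axis, percent of list members), with exact 95% intervals as error bars and listed and measured members in parentheses; blue lists passed Fisher's exact test against all protein-coding genes, and the dashed line marks the 3.47% of all these genes. Tubulins and microtubule proteins (39.1%) and neuronal transcription factors (38.3%) stand at the top; the IGF2BP family list is not drawn.

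Of the reported targets of IGF2BP proteins, 5 of 20 were listed (25%, odds ratio 9.31, Fisher's exact adjusted p = 0.00124): Actb, Cfl1, Gap43, Pabpc1 and Mapt. All 5 are also members of the actin, guidance effector, RNP granule or microtubule lists that passed, so this call is not separate from theirs. The beta-actin gene Actb, whose transcript is carried to growth cones by the family member IMP1, had 4 clusters in its 3' UTR, the highest (45, fold 8.67) on chromosome 5 at 143664909 to 143664965. Cfl1 (36), Gap43 (27) and Pabpc1 (22) had 1 cluster each. Igf2, the transcript after which the family is named, was not listed, nor were Igf2bp1, Igf2bp2 and Igf2bp3 (0 of 3). The call for reported targets was lost with taller clusters, with genes of at least 2 clusters and against the other fixed-list genes (odds ratio 1.78). In the first 2 of these settings 2 of 20 were listed. The odds ratios there were 5.86 and 7.04 (Fisher's exact adjusted p = 0.113 and 0.0819).

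Within the listed genes, the cytoskeletal groups also had taller clusters than random sets. The 14 actin genes had a median height of 44.5 against 32.1 for random sets of listed genes, and the 18 microtubule genes 43.5 against 32 (2-sided permutation tests, adjusted p = 0.0309 for both over 16 lists). The height of a gene is that of its highest cluster, and the random sets were not matched on the number of clusters. At least 2 clusters were held by 9 of these actin genes and 14 of these microtubule genes, against 342 of all 761 listed genes. Taller clusters thus cannot be told apart from more clusters here. Wnt genes (45.5) and insulin and IGF genes (43) did not pass (permutation adjusted p = 0.0797 and 0.131) but did with the sum over the clusters of a gene (permutation adjusted p = 0.0356, range 0.0356 to 0.789 over the alternatives, and 0.0321, range 0.0321 to 0.453), and guidance ligands had the lowest median, 23 (permutation adjusted p = 0.194). The calls depended on the score. With the mean of log2 height actin genes no longer passed (permutation adjusted p = 0.0818, range 0.0321 to 0.661 over the alternatives), and with the highest fold in place of height the microtubule genes did not differ from random sets (median fold 6.50 against 6.50, permutation adjusted p = 0.99, range 0.0321 to 0.99) while matrix genes did (10.6 against 6.54, permutation adjusted p = 0.0211, range 0.0211 to 0.894).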

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

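The backgrounds of NM genes, genes with a 3' UTR cluster, shared clusters counted once, fold in place of height, joining at 50 bases and the other settings of the position test were chosen after the data were seen; the rest were planned. Of the 18 lists that passed, 18 passed against NM genes, 17 with 3' UTR genes, 17 with genes that share a cluster counted once, 12 with clusters taller than the median, 10 with genes of at least 2 clusters and 5 against the union of the lists. Position in the 3' UTR stayed without a call in every setting run. Taller clusters (857 in 409 genes) had 96.4% in 3' UTRs and 3.38% in the CDS, and the erythroid odds ratio was 0 with them and 0 with genes of at least 2 clusters. The number of lists passing was 11 with at least 2 clusters, where fewer genes are listed, and 8 against the union, of which 15.9% are listed against 3.47% of all genes. Against the union, odds ratios went below 1 for guidance ligands (0.921), translation factors (0.958), motors (0.652), presynaptic (0.594) and postsynaptic proteins (0.262), channels (0.294), glycolysis (0.274), cell cycle (0.443), endothelial (0.274), glial (0.656) and choroid plexus markers (0.477). The height test called 4 lists with sums over clusters, 1 with mean log2 height and 1 with fold. Chaperones turned to -12.3 against random sets with the sum; with fold, differences turned for guidance ligands (1.66), microtubule proteins (-0.00943), chaperones (-0.213), Wnt (-0.592) and reported targets (0.708). For these changes of score and of height, the cause was not tested. Length-matched backgrounds, motif settings and library settings were not run. Unknown depth limits all heights, and lists with few listed members have wide intervals.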

Other observations

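The tests of symbol families, of imprinted genes, of abundance, of the pooled set's folds, of the fold's denominator, of 3' UTR length against clusters and of joined clusters were chosen after the results were seen; those of 3' UTR length in list members, of taller clusters and of deeper coverage were set before theirs were seen.

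Small GTPases of membrane traffic were not a fixed list of their own, though Rab3a was in the presynaptic list. Among 660 families of genes with a shared symbol stem, 12 of 69 Rab genes carried clusters (17.4%, 95% interval 9.32 to 28.4, odds ratio 5.93, Fisher's exact adjusted p = 0.000895). Rab11a (height 37) of recycling endosomes, Rab14, Rab18 and Rab1a (36 each) had the tallest. The Rab share was not tested against the fixed-list genes, of which 15.9% were listed. Olfactory receptors (0 of 1110), vomeronasal receptors (0 of 355) and predicted Gm genes (0 of 1329) passed in the other direction. Whether these genes are expressed in this tissue was not measured. Gm genes may be missing from the authors' RefSeq release, and a listed Gm name could be replaced by the current symbol, as at Usf3. These zeros therefore tell nothing of a preference of IMP2.

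Imprinted genes, which are expressed from a single parental copy, were tried because Nnat led the list. Of 40 imprinted genes, 8 were listed (20%, 95% interval 9.05 to 35.6, odds ratio 7.01, Fisher's exact p = 5.88e-05): Nnat (107), Mest (68), Grb10 (63), Peg10 (50), Peg3 (43), Ndn (39), Inpp5f (38) and Plagl1 (19). Their median height was 46.5 against 32.4 for random listed genes (2-sided permutation test, p = 0.0105), a set that includes the gene that prompted the test. Against the union of the fixed lists the odds ratio was 1.32 (Fisher's exact p = 0.509), so imprinted genes may be listed no more readily than other genes chosen for a role in brain or basic cell functions. No biological explanation was tested.

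Neuronal and cytoskeletal lists stood above all protein-coding genes, and abundance or length of their transcripts could account for this. Of 197 genes taken as abundant in every cell (ribosomal, oxidative phosphorylation, glycolysis and proteasome), 1.52% were listed (95% interval 0.315 to 4.39) against 3.49% of other genes. Few of these genes were thus listed, but the interval includes the share of other genes. Their abundance was not measured and the length of their 3' UTRs was not compared, so these values cannot decide whether abundance plays a part. The 3' UTRs of listed members of the lists that passed were longer than those of other listed genes by 171.5 bases in the median (2151.5 against 1980, 2-sided permutation test, p = 0.37), which leaves length open because unlisted genes were not compared. No input library was used here, so abundance in this tissue cannot be told apart from preference of IMP2. No biological explanation was tested.

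High folds were seen at Rgs5 (23.1), Col1a1 (20) and Col3a1 (18.6), and the 15 listed genes of the matrix, vessel, meningeal, choroid plexus and blood lists, pooled after these were seen, had a median fold of 9.61 against 6.43 in 746 others. Most of them, 9 genes with a median of 10.6, were matrix genes, while the globin genes Hba-a1 and Hba-a2, which share a cluster (6.39), and Hbb-y (3.23) lay below the median of the others. The difference in median height was 3 (34, exact 95% interval 27 to 47, against 31, permutation p = 0.547). The folds would need a height of 46.3, just inside that interval, so taller clusters stay open for the set. However, 11 of the 15 genes had heights below 46.3, and Col1a1 (20) and Col3a1 (29) lay below 31. The denominator, height divided by fold, differed by -1.71 (3.54 against 5.25). With folds that differ and heights that are close, a lower denominator follows by arithmetic. It is therefore part of the high folds rather than separate evidence on their cause. Ncan, Sparcl1 and Zic1 are also made by neural cells, what the reference level measures is not given in the sources used here, and no biological explanation was tested.

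The many clusters of genes such as Dcx and Fzd3 might reflect long 3' UTRs, deep coverage or broad signal split into pieces. Splitting at gaps of at most 50 bases is argued against as the whole cause. The 37 genes with at least 8 clusters went from a median of 10 to 8 (range 3 to 25) after such joining. Wider gaps were not tried, so these values cannot decide whether broad signal was split into pieces further apart. Across 729 genes the number of clusters rose with 3' UTR length (Spearman's rho = 0.214), and across 761 genes with the implied denominator of the fold (rho = 0.33), each with a 2-sided permutation p = 0.0001, the smallest that 10000 permutations can give; genes are not independent replicates. The relation with length was weak, so length may contribute in part. Coverage stays open, since the meaning of the denominator is not given in the sources used here, and no biological explanation was tested.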
